A study of Mus musculus with 7 samples.

How the data were processed

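Single-cell messenger RNA profiles of mouse embryonic fibroblasts (MEFs, cells grown from mouse embryos) were measured by Drop-seq, in which single cells share droplets with barcoded beads. The cells were of the ICR background, uninfected and not transformed, and had been incubated for 7 days. All 7 libraries were technical replicates of 1 biological replicate, so the series held 1 group and no contrast between conditions. The p-values therefore measure only the spread between technical libraries of 1 culture.

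The deposited values were whole-number counts per gene and cell barcode, which the authors had not normalized, in 1 table per library. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.5.3a, UMI-tools and featureCounts 1.5.3 were used with genome build mm10. The role of each tool, the annotation, the strand setting and the rule that chose the barcodes were not given in the sources used here. Whether reads with the same molecular identifier had been collapsed was not given either. If they had not, the counts are not independent molecules, the intervals and floors below are too narrow, and the 2 random portions of a cell described below share molecules. Intervals and floors cover counting error only.

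The tables held 27999 gene rows, of which 27645 were matched to a symbol through a table of gene names. The 354 without a symbol included a row for EGFP, which had a total of 0 counts. A barcode was kept with at least 500 counts and at most 20% of counts from mitochondrially encoded genes, which removed none of the 1362 barcodes. The 7 libraries held 344, 208, 292, 204, 110, 110 and 94 cells in the order of their replicate numbers. Their total counts ranged from 1616702 to 3776367, and the counts of single cells from 2326 to 177427. A count of 0 over all libraries allows a level of up to 0.160 CPM (counts scaled to the same total in each library), taking 3 counts as the floor, and 0 cells allow a share of up to 0.2203%. Scrublet, run per library in scanpy 1.11.5, called 50 doublets, which were kept except in an alternative.

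Levels are CPM of the counts summed over each library, given as mean ± SD over 7 libraries, with shares of cells that had a count and their 95% Wilson intervals. Agreement of the libraries was measured by Pearson's r of log2(CPM + 1), by edgeR's common dispersion, and by a chi-square test per gene of equal shares over libraries with Benjamini-Hochberg adjustment. For tests between classes of cells, the counts of each cell were divided binomially with probability 0.5 and a fixed seed. The class portion was used only to class or cluster cells, and the held-out portion only for sums and tests.

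Cells called S or G2M by scanpy's cell-cycle scores were set against cells called G1. Cells in the top tercile of the share of counts from 10 contractile genes were set against the bottom tercile, ranked within each library and within 3 bins of depth. Clusters came from Leiden clustering with igraph 0.11.9 on 2000 variable genes, 20 principal components and 15 neighbours at resolution 0.5, without correction between libraries. A planned permutation test of cluster shares over libraries took cells as its units and is not reported. A cluster took a cell-type name only from marker lists, where at least 3 markers rose and its leading genes did not go against the name. A name here also needed a marker among the 10 leading genes by fold, a condition set after the data were seen, without which cluster 5 would be called fibroblast-like. The condition also bore on cluster 4, where 3 of 10 fibroblast markers rose and 2 fell, with 0 among its 10 leading genes.

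Sums per library and class were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, library as a block, Benjamini-Hochberg adjusted p under 0.05). A library entered where both classes had at least 10 cells. Genes that defined a class list were left out of that test. Libraries with numbers below 500 in the labels (replicates 1 and 2) were set against those above it (replicates 3 to 7) in a fit without a block, as a check of technical batches. The 33 fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, in lists with at least 3 tested members. Gene and marker lists, tests, classes, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives added afterwards were cells with at least 5000 counts, cells thinned to 2000 counts, fits within each run of library numbers, and the interaction of class with run.

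The rule named the 15 genes with the highest mean CPM outside the ribosomal protein and mitochondrially encoded lists, and up to 4 members of each list with the highest CPM. For each test it named the 8 genes with the largest change in each direction (5 up and 3 down for a cluster) among those past the threshold, with a mean of at least 100 CPM and the same direction in every library. Between runs of library numbers, both libraries of the first run had to lie outside the range of the other 5. Genes named outside this rule are said to be so. The single-gene results of 1 gene that the rule selects are not reported here.

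Transcript lengths and near-identical copies were taken from the GENCODE M21 transcripts, with a copy counted at 95% identity over at least 100 nt of the last 500 nt (blastn 2.17.0). Medians of gene classes carry 95% bootstrap intervals from 2000 draws. Genes with near-identical copies, among them Rpl41, Rpl38, Rps28, Ptma, Eno1, Ftl1, Tuba1b, Igf2, Lyz2 and Ly6a, are uncertain because the counting could split their reads. Because the strand setting is unknown, so are genes that overlap another gene on the other strand, among them Wdr38, Myom2, Rpl28, Rpl35a, Prc1, Pclaf, Acta1, Des, Mki67, Top2a, Cdkn1c, Sned1, H19 and Xist.

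The tests were tried on simulated data drawn from the real means, library sizes and dispersion with 200 genes changed. Among 12076 genes simulated for the library runs, 10.4% of 1.5-fold, 59.7% of 2-fold and 95.5% of 4-fold changes were recovered. For cycling against G1 cells (7889 genes) these shares were 58.2%, 91.0% and 89.4%, and for the contractile classes (7159 genes) 55.2%, 85.1% and 92.4%. For cluster 7, with 2 libraries and 8341 genes, they were 0%, 1.49% and 25.8%. Among the unchanged genes of these simulations there were 3 false calls for the runs, 4 for cycling cells, 9 for contractile cells and 0 for cluster 7. With no gene changed, edgeR made 0 calls in each of these tests, and with cells drawn without structure and then classed it made 0 calls for cycling and for contractile cells. Permuted fold changes of 11998 genes gave a median of -0.08 (-0.16 to 0.01) for the 237 short genes, and -1.08 after a shift of -1 was added. Alternatives included DESeq2 1.42.0, other scaling, no filter on low counts, other cell filters, leaving out each library, other seeds and other class rules.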

Results

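The series profiled uninfected MEFs, the starting cells of a study that screened combinations of transcription factors for conversion towards cardiac cells. It held 1362 cells and 18725010 counts in 7 technical libraries of 1 culture. Median counts per cell were 7004.5, 9547, 4879, 11968.5, 24547.5, 11439 and 17243.5 in libraries 1 to 7, and a median of 3789 genes per cell had a count. With 1 group, the comparisons are of levels, of libraries and of classes of cells within the culture.

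The first question was what these cells express before any factor is added. Fibroblast matrix and cytoskeletal genes stood among the most abundant transcripts. After the nuclear RNA Malat1 (10616 ± 3680 CPM, mean ± SD, n = 7) came Sparc, a collagen-binding matrix protein, at 5935 ± 501 CPM, Actb (beta-actin) at 5925 ± 850 and Tmsb4x, an actin-binding peptide, at 5173 ± 1275. The collagen I chains Col1a2 and Col1a1 reached 5143 ± 1460 and 2993 ± 650 CPM and had a count in 99.6% (95% Wilson interval 99.1 to 99.8) and 99.2% (98.6 to 99.6) of cells. Smooth-muscle actin Acta2 stood at 3783 ± 743 CPM with a count in 95.3% of cells, tropomyosin Tpm1 at 3495 ± 215 and the intermediate filament gene Vim at 3343 ± 742. The imprinted genes H19 and Igf2 were at 4180 ± 819 and 3341 ± 608 CPM. Ftl1, Lgals1, Cald1 and S100a6 completed the 15 most abundant, at 4873 ± 835, 4156 ± 1236, 3505 ± 373 and 3310 ± 1094 CPM.

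Cardiac genes were low or at 0. The cardiac transcription factors Gata4, Tbx5 and Hand2, singled out here because of the study's cardiac aim, had 1.34 ± 0.44, 2.83 ± 1.44 and 5.06 ± 1.89 CPM and a count in 1.54%, 2.86% and 3.96% of cells (n = 7 libraries). Mef2c, another factor of this group, had 20.97 ± 4.36 CPM with a count in 20.1% of cells (4.92% with each cell thinned to 2000 counts), and Nkx2-5 had 0 counts in 1362 cells. This allows up to 0.2203% of such cells to show a count, but at this depth low expression can be missed in cells that have it. Over the whole list of cardiac transcription factors, which also holds widely expressed genes, the sum was 354 ± 26.8 CPM, led by Mef2a at 149 ± 17.1, Meis1 at 52.3 ± 9.41 and Srf at 32.0 ± 7.16. The 15 sarcomere and natriuretic peptide genes of the cardiomyocyte list summed to 27.5 ± 14.4 CPM. Its troponin gene Tnnt2 had 109 counts in 40 cells, of which 53 came from 1 cell. The liver gene Alb and the globin gene Hbb-bs had a count in 0.0734% of cells each at the median depth of 9383 counts per cell. These 2 cannot measure the free RNA of genes that the culture itself expresses, so the share of low cardiac counts that came from free RNA is not known.

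Lists of other cell types were measured in the same sums (mean ± SD, n = 7). The fibroblast list summed to 13274 ± 1390 CPM and the contractile list to 11500 ± 1862. Far below these lay endothelial or endocardial genes at 80.6 ± 13.9, epicardial or mesothelial genes at 230 ± 102, macrophage or leukocyte genes at 62.4 ± 54.5 and erythroid genes at 2.19 ± 1.58 CPM. Epithelial genes stood at 23.5 ± 16.3 CPM, chondrocyte genes at 101 ± 14.2, adipocyte genes at 216 ± 25.2, neural or glial genes at 331 ± 60.7, pericyte genes at 229 ± 24.6 and hepatocyte genes at 0.201 ± 0.274. The skeletal muscle sum of 169 ± 78.6 CPM was mostly Acta1 (164 ± 79.5), and the osteoblast sum of 2423 ± 1206 CPM mostly Spp1 (2398 ± 1207).

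Among the state lists, collagen and matrix genes summed to 25611 ± 986 CPM, ribosomal protein genes to 55334 ± 13371, imprinted growth genes to 11549 ± 1455, unfolded protein genes to 6963 ± 564 and mitochondrially encoded genes to 5073 ± 328. TGF-beta response genes stood at 4138 ± 840 CPM, G2M genes at 3566 ± 513, p53 response genes at 3371 ± 170, glycolysis genes at 3346 ± 759, histone and chromatin genes at 2766 ± 225 and interferon response genes at 2504 ± 489. Cholesterol synthesis genes summed to 1828 ± 222 CPM, chemokine and inflammatory genes to 1664 ± 338, limb and positional transcription factors to 1362 ± 136, S-phase genes to 1351 ± 189, immediate early genes to 1228 ± 157 and pluripotency genes to 138 ± 24.1. The limb bud factor Prrx1 had 549 ± 87.7 CPM, and the p53 target Cdkn1a 934 ± 211. Klf4 and Myc made up most of the pluripotency sum, with 91.4 ± 22.3 and 45.8 ± 25.1 CPM.

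The technical libraries varied by more than counting noise, to which the different cells in each add. Over 10484 genes, Pearson's r of log2(CPM + 1) between libraries ranged from 0.927 to 0.979 with a median of 0.957, a description across genes, which are not independent replicates. The common dispersion was 0.0434, a variation of 20.8% beyond counting. A chi-square test per gene found unequal shares over the libraries for 7145 genes, 68.2% of those tested. Because each library holds other cells (94 to 344), such an excess arises without any technical difference, as for Tnnt2, with 53 of 109 counts in 1 cell.

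The check for technical batches set the 2 libraries with the lower library numbers against the other 5. Ribosomal protein genes were lower in libraries 1 and 2, with a summed level of 34607 and 41289 CPM against 57249, 64343, 63401, 72483 and 53966 CPM in libraries 3 to 7. Rpl38, a protein of the large ribosomal subunit, fell from 630 ± 189 CPM (n = 5) to 77.7 ± 24.9 (n = 2), a log2 fold change of -3.01 ± 0.31 (SE, adjusted p = 0.000154 by edgeR). Rps28, Rpl35a, Rpl41, Rpl36 and Rpl28 changed by -2.66, -2.48, -2.42, -2.33 and -2.23. Of 88 tested list members, 50 fell and 0 rose (61 fell adjusted over the list alone), with a median of -0.94. The camera test of the list gave an adjusted p of 1.08e-45, and adjusted p = 0.592 with an estimated correlation. The list rule also takes in S6 kinases and other look-alike symbols, and the 79 genes without them had a median of -1.02. Near-identical copies make single members uncertain.

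Among other genes the change was largest in short transcripts. Over all of them the change had almost no rank relation with the length of the longest transcript (Spearman's rho = -0.0173), while the bins here use the principal transcript. Genes outside the list had a median log2 fold change of -1.12 with a principal transcript under 500 nt (63 genes), -0.69 from 500 to 700 nt (171), -0.18 from 700 to 1000 nt (460), 0.03 from 1000 to 1500 nt (1080) and -0.01 above (9735). Ribosomal protein genes in the same bins had -1.52, -1.20, -0.74, -0.77 and -0.99, from 10, 20, 27, 13 and 9 genes.

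**Figure D1:**
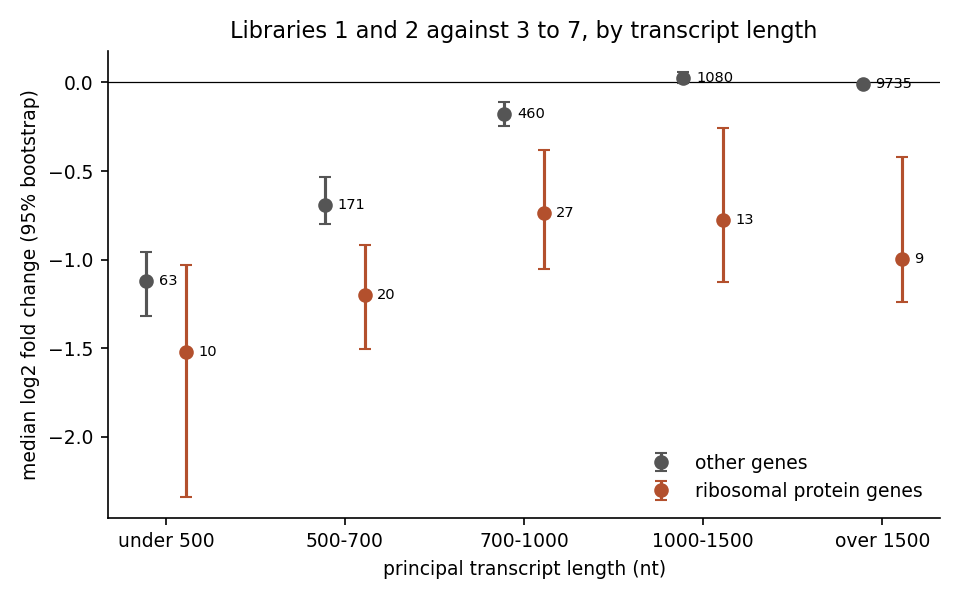
Median log2 fold change of libraries 1 and 2 against libraries 3 to 7 by length of the principal transcript, with 95% bootstrap intervals, for ribosomal protein genes and all other genes. In the shortest bin the medians are -1.52 and -1.12, and above 1500 nt they are -0.99 and -0.01.

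**Figure D2:**
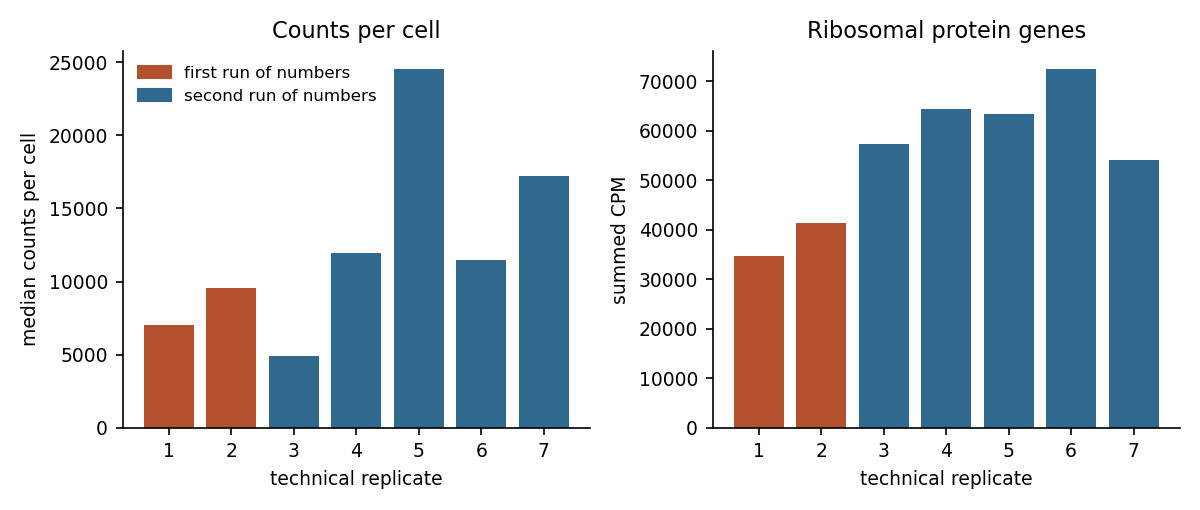
Median counts per cell (left) and the summed CPM of the ribosomal protein list (right) in each technical replicate, coloured by the run of library numbers. The ribosomal sums of replicates 1 and 2, 34607 and 41289 CPM, lie below those of replicates 3 to 7, 53966 to 72483 CPM, while depth follows no such order.

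Outside the ribosome, Wdr38 and Myom2 changed by -2.52 and -2.48 between the runs. Wdr38 overlaps Rpl35 on the other strand, and Rpl35 itself changed by -2.14, so the reads of this pair cannot be told apart. Among genes that met the naming rule, which requires a mean of at least 100 CPM, those with the largest rise in libraries 1 and 2 were Ppp4c, a phosphatase subunit (log2 fold change 1.10 ± 0.24, adjusted p = 0.0159), the secreted phosphoprotein Spp1 (1.03 ± 0.25), the purine salvage gene Hprt (1.02 ± 0.17) and the matrix proteoglycan Lum (0.99 ± 0.21). Yipf4, Cav1, Stard3nl and Sdcbp rose by 0.96, 0.94, 0.92 and 0.91. Of the glycolysis genes, 6 of 16 fell (6 adjusted over the list alone), among them Eno1 (-1.39 ± 0.30). Of the histone and chromatin genes, 3 of 15 fell and 0 rose (7 fell and 2 rose adjusted over the list alone), with Ptma at -1.80 ± 0.30. Neither list passed camera (adjusted p = 0.0533 and 0.0749). The interferon response list had 2 of 11 members lower (2 adjusted over the list alone), with Bst2 at -1.33 ± 0.28. Of 43 S-phase genes 2 rose (2 adjusted over the list alone), and of 11 chemokine and inflammatory genes 0 rose (4 adjusted over the list alone). The pericyte gene Rgs5 rose by 1.29 ± 0.25 and Cspg4 fell by 0.79 ± 0.19, and Myc rose by 1.24 ± 0.22. No other list passed camera, the lowest adjusted p being that of glycolysis.

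In all, 279 of 12111 genes were higher and 608 lower in libraries 1 and 2 (edgeR, adjusted p under the threshold). Single libraries set the size of these counts. The higher genes numbered 77 without replicate 1, 11 without replicate 2, 105 without replicate 4, 440 without replicate 5 and 141 without replicate 6, and the lower genes 123 without replicate 1 and 215 without replicate 2.

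Cycling cells were compared with cells called G1 to describe the proliferative part of the culture. Prc1, which bundles microtubules of the mitotic spindle, rose from 9.97 ± 4.27 to 380 ± 96.7 CPM (mean ± SD, n = 7 libraries), a log2 fold change of 5.21 ± 0.16 (SE, adjusted p = 1.78e-19 by edgeR). The replication factor Pclaf rose by 4.40 ± 0.14, the separase inhibitor Pttg1 by 3.91 ± 0.19, the kinetochore gene Spc25 by 3.84 ± 0.16, the condensin subunit Smc2 by 3.60 ± 0.10 and the cyclin Ccna2 by 3.35 ± 0.14. Incenp and the histone methyltransferase Ezh2 rose by 3.56 and 2.51. Among the genes that fell were the nuclear RNA Neat1 (-1.19 ± 0.13), the cyclin-dependent kinase inhibitor Cdkn1c (-1.12 ± 0.11), the MYC-network repressor Mxd4 (-1.04 ± 0.10) and the stress factor Ddit3 (-0.80 ± 0.14). Hist1h2bc, Gm26735, Grina and Impact changed by -0.88, -0.86, -0.83 and -0.82. All 16 moved the same way in 7 of 7 libraries, which the rule that named them required.

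A fixed list of histone variant, chromatin and other growth-related genes, among them tubulins, rose in all 13 tested cases (13 adjusted over the list alone). Examples are Tuba1b (1.37 ± 0.09) and Ran (0.92 ± 0.08) and, named outside the rule, the histone variant H2afx (1.89 ± 0.11) and the DNA methyltransferase Dnmt1 (2.56 ± 0.17). Histone genes outside the list did not all rise, since Hist1h2bc fell as given above. The list had a camera adjusted p of 5.48e-47 and adjusted p = 0.00145 with an estimated correlation. Cholesterol synthesis genes fell in 8 of 11 cases (10 adjusted over the list alone), with Msmo1 at -0.53 ± 0.09 and Cyp51 at -0.45 ± 0.09 (camera adjusted p = 0.00314; adjusted p = 0.0948 with an estimated correlation). TGF-beta response genes fell in 5 of 11 cases (6 adjusted over the list alone), with Thbs1 at -0.57 ± 0.09 (adjusted p = 0.00703, and adjusted p = 0.120 with an estimated correlation). Of the collagen and matrix genes, 9 of 25 fell (12 adjusted over the list alone), with Fn1 at -0.46 ± 0.07 and Sparc at -0.26 ± 0.06 (adjusted p = 0.00986, and adjusted p = 0.318 with an estimated correlation).

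Imprinted growth genes fell in 4 of 11 cases (5 adjusted over the list alone), with Meg3 at -0.68 ± 0.08 and Igf2 at -0.35 ± 0.08, which turned to 0.0368 with classes from cells thinned to 500 counts (adjusted p = 0.0136, and adjusted p = 0.440 with an estimated correlation). Contractile genes fell in 3 of 10 cases (5 adjusted over the list alone; adjusted p = 0.0165, and adjusted p = 0.661 with an estimated correlation), and immediate early genes in 3 of 10 (4 adjusted over the list alone; adjusted p = 0.0308, and adjusted p = 0.318 with an estimated correlation). The G1 class, however, held 241 of the 269 cells of the contractile cluster 2 described below. Cluster 1, of mostly cycling cells, held 91 contractile-high and 60 contractile-low cells. The falls of contractile and TGF-beta response genes can therefore not be told apart from the mix of cells in each class. Mesothelial markers rose in 3 of 3 cases (3 adjusted over the list alone), with Upk1b at 1.84 ± 0.35 and Msln at 1.33 ± 0.28 (adjusted p = 0.0444, and adjusted p = 0.5003 with an estimated correlation). Cycling cells held 21 of the 53 cells of the mesothelial-like cluster described below, Msln rose in 6 and Upk3b in 5 of 7 libraries, and Upk1b stood at 122 ± 156 CPM in cycling cells. Of 82 ribosomal protein genes 3 rose and 0 fell (0 adjusted over the list alone), with a median of 0.02. Of the p53 response genes 4 of 13 fell (5 adjusted over the list alone; camera adjusted p = 0.0619), of the glycolysis genes 3 of 13 (3) and of the chemokine and inflammatory genes 2 of 7 (2, with 1 higher).

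In this comparison 750 of 7882 genes rose and 565 fell. Within libraries 1 and 2 the counts were 489 and 158, and within libraries 3 to 7 they were 609 and 425. The effect of class differed between the runs for 7 genes by edgeR's interaction test (443 at an unadjusted p under 0.05), among them Apoe, H19 and Ccl2. The class is a range of a score, in which 56 of 379 cycling and 121 of 983 G1 cells lay within 0.05 of the boundary, and median depths were 8279 and 10115 counts. The calls also depended on depth. With cells thinned to 500 counts, 341 of the 379 cycling and 691 of the 983 G1 cells kept their class. With classes from all counts, 332 and 966 did. DESeq2 called 516 genes higher and 273 lower, and a fit without the replicate block 402 and 105.

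**Figure D3:**
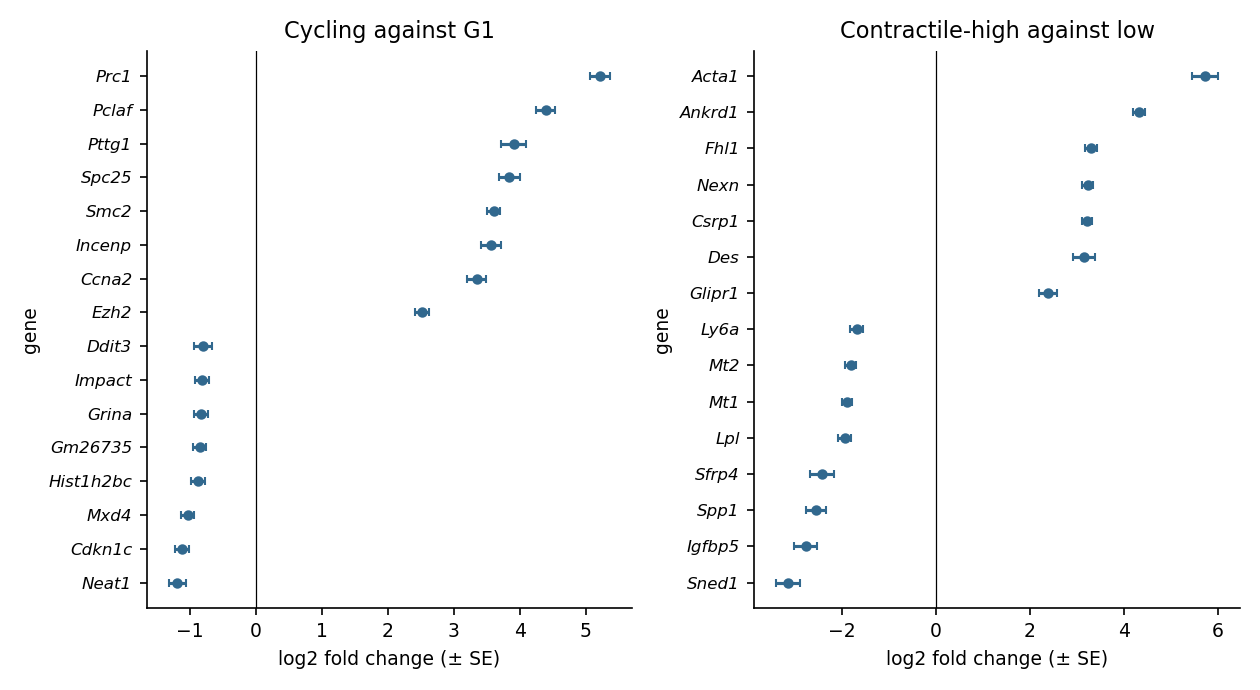
Log2 fold changes with standard errors of leading genes in the tests of cycling against G1 cells (left) and of contractile-high against contractile-low cells (right), over 7 libraries. Prc1 at 5.21 and Acta1 at 5.73 show the largest rises, Neat1 at -1.19 and Sned1 at -3.13 the largest falls among them.

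The contrast of contractile-high with contractile-low cells asked which genes vary with the contractile program of the culture. Skeletal actin Acta1 rose from 9.91 ± 9.95 to 456 ± 252 CPM (mean ± SD, n = 7), a log2 fold change of 5.73 ± 0.27 (SE, adjusted p = 7.43e-14 by edgeR), although its coding sequence resembles that of other actins. The mechanosensitive nuclear gene Ankrd1 rose by 4.32 ± 0.13, the LIM-domain genes Fhl1 and Csrp1 by 3.31 ± 0.13 and 3.22 ± 0.12, the actin-binding gene Nexn by 3.23 ± 0.12, and the muscle intermediate filament Des by 3.15 ± 0.24. Glipr1 rose by 2.39 ± 0.19. Lower in contractile-high cells were the matrix gene Sned1 (-3.13 ± 0.25), the growth factor binding protein Igfbp5 (-2.76 ± 0.24), Spp1 (-2.54 ± 0.22), the WNT antagonist Sfrp4 (-2.41 ± 0.26) and lipoprotein lipase Lpl (-1.94 ± 0.15). The metallothioneins Mt1 and Mt2 and the surface antigen Ly6a changed by -1.89, -1.81 and -1.68. Each gene named here moved the same way in 7 of 7 libraries, again because the naming rule required it.

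TGF-beta response genes rose in 5 and fell in 2 of 11 cases (5 and 2 adjusted over the list alone), with Ccn2 at 2.27 ± 0.11 and Thbs1 at 1.25 ± 0.09 (camera adjusted p = 8.26e-09; adjusted p = 0.0675 with an estimated correlation). Fibroblast genes rose in 2 and fell in 5 of 10 cases (2 and 5 adjusted over the list alone), with Col3a1 at -0.60 ± 0.10 (adjusted p = 0.0121, and adjusted p = 0.468 with an estimated correlation). S-phase genes rose in 7 of 20 cases (11 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.518 with an estimated correlation). Chemokine and inflammatory genes rose in 2 and fell in 1 of 5 cases (2 and 1 adjusted over the list alone), with the inflammatory gene Ptgs2 at 2.26 ± 0.15 and the chemokine Cxcl12 at -0.38 ± 0.10 (adjusted p = 0.0480, and adjusted p = 0.385 with an estimated correlation). Collagen and matrix genes went both ways, with 6 higher and 9 lower of 25 (7 and 9 adjusted over the list alone).

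Imprinted growth genes fell in 5 of 11 cases (7 fell and 2 rose adjusted over the list alone), H19 by -0.61 ± 0.09, and mesothelial markers in 3 of 3 (3 adjusted over the list alone), with camera adjusted p = 0.0662 and 0.110. The mesothelial result was unstable, since Upk1b fell in 4 and Upk3b in 5 of 7 libraries, and they turned to 0.74 and 0.33 with classes from cells thinned to 500 counts. Srf, a transcription factor of muscle and cytoskeletal genes, rose by 0.87 ± 0.23, the only one of 4 tested cardiac transcription factors that did. Both tested adipocyte genes fell, Fabp4 by -2.40 ± 0.22 and Lpl as above. Of 41 G2M genes 5 rose (5 adjusted over the list alone), while 745 of all 7055 tested genes did. The G2M list did not pass camera (adjusted p = 0.0662, and adjusted p = 0.718 with an estimated correlation). Higher were also 5 of 13 glycolysis genes (5 adjusted over the list alone), 4 of 11 cholesterol synthesis genes (4) and 5 of 11 unfolded protein genes (5, with 1 lower). Immediate early genes fell in 4 of 10 cases (5 adjusted over the list alone), Fos by -0.80 ± 0.12, and limb and positional factors in 3 of 13 (3). Among single members of other lists, the endothelial gene Emcn rose by 2.82 ± 0.28, the neural gene Nes by 1.93 ± 0.11 and the pericyte gene Mcam by 2.76 ± 0.25, while Pdgfrb fell by 0.68 ± 0.13. Of 81 ribosomal protein genes, 1 rose and 3 fell (0 and 1 adjusted over the list alone).

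Here 745 of 7055 genes rose and 704 fell. Within libraries 1 and 2 the counts were 526 and 540, and within libraries 3 to 7 they were 425 and 416. No gene showed a class effect that differed between the runs (0 by edgeR, 251 at an unadjusted p under 0.05). The classes are the ends of a range, with a median list share of 1.71% in 447 high cells and 0.244% in 447 low cells. DESeq2 called 432 higher and 378 lower, and a fit without the replicate block 345 and 366.

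Clustering was used to describe what the culture holds, and it gave 7 clusters of 254, 269, 117, 284, 304, 81 and 53 cells. Cluster 1 was led on the held-out counts by Ckap2l at a log2 fold change of 5.73 ± 0.18, Nusap1 at 5.45, Kif23 at 5.43, Ccnb1 at 5.33 and the proliferation marker Mki67 at 5.23 ± 0.15 (n = 7 libraries). Of its 254 cells, 249 were also called cycling. Neat1, Mxd4 and Acta1 were lower in it (-1.60, -1.35 and -1.35). Cluster 2 was contractile smooth muscle or myofibroblast-like. All 10 contractile markers were higher (10 adjusted over the list alone), among them smooth-muscle myosin Myh11 (5.15 ± 0.20), Actg2 (3.96 ± 0.23) and calponin Cnn1 (3.39 ± 0.16), together with Acta1 (3.97) and Ankrd1 (3.80). Top2a, Igfbp5 and Spp1 were lower in cluster 2 (-3.74, -2.67 and -2.26), and 209 of its 269 cells were contractile-high. Clusters, phase calls and contractile classes all came from the class portion of the counts, so these overlaps of cells are not independent support.

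Cluster 7 was epicardial or mesothelial-like. Of 6 tested markers 5 rose (5 adjusted over the list alone): Wt1, Msln and the leading genes Lrrn4 (9.78 ± 0.76), Upk1b (9.10 ± 0.61) and Upk3b (8.79 ± 0.58). The list had a camera adjusted p of 1.27e-101, and adjusted p = 0.646 with an estimated correlation. Aldh1a1, a retinaldehyde dehydrogenase, and the membrane protein Gpm6a rose by 8.08 and 8.06. On the held-out counts Upk3b had a count in 83.0% of its cells (95% Wilson interval 70.8 to 90.8) and in 1.53% (0.991 to 2.35) of other cells. Median depths before the counts were divided were 8389 and 9418 counts. Crabp1, a retinoic acid binding protein, had 0 held-out counts in the 2 libraries tested, at least 11.9-fold below the other cells there with 3 counts over the cluster as the floor. Over all 7 libraries, however, 8 of the 53 cells had a held-out Crabp1 count (15.1%), against 43.5% of other cells. Acta1 and Spp1 changed by -4.48 and -4.03. This test rested on 2 libraries with at least 10 such cells.

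The other 4 clusters were given no cell-type name, for lack of a marker among their 10 leading genes or of enough markers that rose. The cells each was set against included clusters 1 and 2, so lower Top2a and contractile genes are relative to those cells. Cluster 3 was led by the chemokine Cxcl14 (2.90 ± 0.32), Crabp1 (2.78 ± 0.21), the WNT antagonist Dkk2 (2.499), the matrix gene Dpt (2.40) and C1qtnf3 (1.99), with Sfrp4, Actg2 and Ankrd1 lower (-3.74, -3.33 and -3.24). Cluster 4 had higher Spp1 (2.07 ± 0.15), Igfbp5 (1.69), the BMP antagonist Grem1 (1.62 ± 0.14), Sned1 (1.57) and the gap junction gene Gja1 (1.19), and lower Top2a, Acta1 and Actg2 (-3.46, -3.20 and -3.11). Its median depth, 6323 counts, was the lowest of the clusters. Cluster 5 was led by Sfrp4 (2.60 ± 0.17), Sncg (1.32), Gas2 (1.19), Sfrp1 (1.13) and the growth factor Igf1 (1.09), and Top2a and Actg2 were lower (-3.08 and -2.93), as was Cnn1. Of the fibroblast markers 8 of 10 rose in cluster 5 and 1 fell (8 and 1 adjusted over the list alone), but 0 were among its 10 leading genes. Cluster 6 had higher ceruloplasmin Cp (3.43 ± 0.24), the interleukin-1 receptor antagonist Il1rn (3.19), Abi3bp (2.93), apolipoprotein Apoe (2.54 ± 0.18) and Lmcd1 (1.98), and lower Acta1, Actg2 and Ankrd1 (-4.76, -4.04 and -3.74).

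The shares of clusters are described without a test, since each library is 1 sample of the same culture. Cluster 2 held 23.3% and 28.8% of cells in libraries 1 and 2 and 11.0% to 21.8% in libraries 3 to 7, and cluster 5 held 17.4% and 15.9% against 24.5% to 27.9%. Clusters were made without correction between libraries, and with library means subtracted only 41.3% of the cells of cluster 2 and 53.95% of those of cluster 5 stayed in 1 cluster. Dividing the counts of each cell with another seed kept 71.4% and 45.4% together. Shares per library under these settings were not computed, so the differences rest on clusters that are not stable. Cluster 1 varied little, at 18.5 ± 1.51% (mean ± SD, n = 7). Phase calls gave 72.2% G1, 14.2% G2M and 13.7% S over all cells, and since depth differs between libraries and calls read free RNA, their shares are not ranked here. Genes higher and lower numbered 884 and 737 in cluster 1, 910 and 769 in cluster 2, 198 and 200 in cluster 3, 295 and 336 in cluster 4, 380 and 503 in cluster 5, 192 and 231 in cluster 6, and 104 and 53 in cluster 7.

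**Figure D4:**
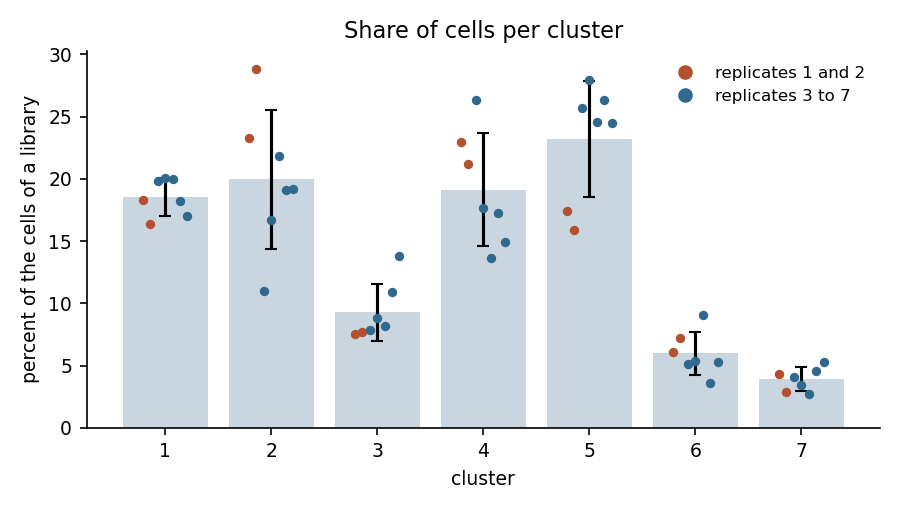
Share of the cells of each library in the 7 clusters, as points per technical replicate, with bars for the mean and error bars for the SD over 7 libraries. Cluster 5 holds 17.4% and 15.9% of cells in replicates 1 and 2 and 24.5% to 27.9% in replicates 3 to 7.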

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

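The tests of length-matched genes, of ribosomal protein genes without copies, of the translation genes against the ribosomal interval, of cluster 7 (its depth and its markers) and of sex-linked counts, and the bounds set for other splits of the samples, were chosen only after the results were seen. Of 62 sets of 7 library values searched for a library far from the others, 2 had one, and chance gives about 1 in 20. The macrophage or leukocyte list summed to 176.6 CPM in technical replicate 7, far above the 43.3 ± 22.7 CPM of the other 6, and 286 of its 351 counts there came from 1 cell with at least 5 list members. H19 stood at 5826.5 CPM in technical replicate 3, above the 3905 ± 415 CPM of the other 6.

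The lower ribosomal protein genes of libraries 1 and 2 went with a fall of other short transcripts: other genes with a longest transcript under 700 nt had a median log2 fold change of -0.80 (-0.86 to -0.67, 237 genes), which fits a lower recovery of short transcripts in those libraries. Matched by annotated length, ribosomal protein genes still lay -0.43 (-0.72 to -0.21) from other genes. The match used principal transcripts of the annotation, not the lengths of the RNA captured, so length as the whole cause stays open. A different mix of clusters is argued against by medians of -0.75 or lower within clusters 1, 2, 4 and 5. Reads shared with copies cannot be the whole cause, because the 13 ribosomal protein genes without a copy had a median of -0.91, but a part stays open, since other genes with copies had a median of -0.17, between the bounds set for it. Genes of translation outside the ribosome did not move by as much (median -0.17, interval from -0.25 to 0.09, 20 genes), although -0.17 also lay between the bounds written for a smaller fall, which stays open. With 1 culture and no label that separates the runs beyond their numbers, no other biological explanation was tested, and a batch of library preparation may add to the length effect of -0.80.

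Cluster 7 could be an artifact of doublets or of free RNA. Doublets with a fibroblast would raise depth, but the ratio of its median counts to those of other cells of the same library was 0.962 ± 0.280 (mean ± SD, n = 7), with a 95% interval of 0.703 to 1.22 that reaches the bound of 1.2, and Scrublet called 2 of its 53 cells. It reached 1.40 and 1.32 in libraries 2 and 5, and 17.0% of its cells had counts of both Xist and Y-linked genes, against 8.15% of all cells, so doublets stay open. The CPM of Upk3b, Upk1b and Lrrn4 was a median of 588.9 times higher in cluster 7, but these genes were chosen for that change. The lowest ratio of held-out shares of cells that the Wilson intervals allow was taken for all 8 markers of the list fixed beforehand. Its median was 17.7 (3.07 for Krt19 to 63.4 for Lrrn4). However, 5 of these markers rose on the same held-out counts and gave the cluster its name. Aldh1a2, Muc16 and Krt19 did not, and had 4.27, 24.2 and 3.07. Free RNA spread over all droplets would give nearly equal shares. The ratios of Aldh1a2, Muc16 and Krt19 argue against it as the whole cause, unless the 2 portions of a cell share molecules. A small population of mesothelial cells in the culture is a hypothesis beside doublets and free RNA.

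Other splits of the samples were run for the counts of changed genes except that of cluster 7, which had 2 libraries. For the library runs, the real split gave 887 genes and the highest of the other 20 splits 2, so that 1 of 21 splits, the real one, was as large, which speaks against chance. For cycling cells, 1 of 64 exchanges of class labels within libraries gave as many as the real 1315 (highest other 197), and for contractile cells 1 of 64 gave as many as 1449 (highest other 305). For clusters 1, 2, 4 and 5 the real counts of 1621, 1679, 631 and 883 were reached by 1 of 64 exchanges each (highest others 261, 426, 110 and 75), and for cluster 3 the 398 genes by 1 of 32 (highest other 9). These classes and clusters were made from the other portion of the counts of the same cells. Their real labels were bound to lead wherever the 2 portions of a cell agree. The exchanges therefore cannot tell whether the groups are distinct, and clusters were not tried on cells drawn without structure. Cluster 6 had 423 genes and a highest other of 1 among 16 exchanges, too few for a share under 0.05.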

How the results depend on the processing

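Fits with cells of at least 5000 counts, with cells thinned to 2000 counts and within each run of library numbers were chosen after seeing the data. Filters of at least 1000 counts and of every deposited barcode removed no cell and so test nothing. Without these 2 filters, 193 of 208 values of leading genes for the library runs, 302 of 304 for cycling cells and 300 of 300 for contractile cells kept their direction and side of the threshold, and the other 15 and 2 fell short of it. Leading genes were chosen for large changes past the threshold, which favours this outcome. Over all named genes of the 3 tests, 5255 of 5613 values kept their side of the threshold. Another 212 fell short of it, 140 came past it and 6 changed direction. Changes of direction short of the threshold in both fits count as kept. DESeq2 shared 788 of the 1315 calls for cycling cells and 810 of the 1449 for contractile cells.

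For the library runs (279 higher, 608 lower), no filter on low counts gave 620 higher, and thinning to 2000 counts 78 higher and 268 lower, with fewer genes tested. Leaving out 1 library gave from 11 (without replicate 2) to 440 (without replicate 5) higher and from 123 (without replicate 1) to 753 (without replicate 5) lower, and the fits without replicate 1 or 2 assume that the lone library varies like the others. The median of the ribosomal protein list ranged from -1.08 (without replicate 2) to -0.70 (without replicate 1) in these fits.

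For cycling cells (750 and 565), the fit with no replicate block gave 402 higher and 105 lower, libraries 1 and 2 alone 489 and 158, the class by G2M counts 480 and 332, classes from cells thinned to 500 counts 389 and 112, and classes and sums from all counts 1289 and 984. DESeq2 gave 273 lower and no filter 879 lower. For contractile cells (745 and 704), the fit with no replicate block gave 345 and 366, DESeq2 432 and 378, libraries 3 to 7 alone 425 and 416, and all counts for classes and sums 1156 and 1093. Where classes and sums share counts, the same counts choose and test. Fewer libraries or cells explain part of the within-run counts by construction; for the other settings the cause was not tested. Leaving out 1 library gave 651 to 736 higher for cycling cells and 74.3% to 88.0% of the 565 lower ones, all below it, and 582 to 777 higher and 557 to 715 lower for contractile cells. The blocked and unblocked fits shared 507 calls of the same direction for cycling and 711 for contractile cells, all those of the unblocked fits.

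Within libraries 1 and 2 alone, the change between cycling and G1 cells turned to 0.64 for Ccl7 and -0.82 for H19. With classes from cells thinned to 500 counts it turned to 0.0368 for Igf2, and for contractile cells to 0.74 for Upk1b and 0.33 for Upk3b. In G1-called cells only, Smc4 turned to -0.0229 between contractile classes. The cause was not tested. At least 50 CPM per gene raised the share of genes beyond counting noise from 68.2% to 94.1% and the variation from 20.8% to 21.8%. Clusters numbered 4 at resolution 0.25 and 12 at resolution 1, and the largest cluster held 62.9% and 16.1% of cells there, against 22.3%. It held 37.0% with 1000 variable genes, 35.7% with library means subtracted, 28.4% without phase genes and 26.1% with another seed for dividing the counts. In each of these, 90.6% to 100% of the cells of cluster 7 stayed in 1 cluster, against 39.8% to 100% for cluster 4.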

Other observations

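The test of sex-linked counts was chosen only after the result was seen, as was the search for close barcodes. The culture appears to hold cells of both sexes. Xist, the RNA of the inactive X chromosome, had a count in 355 cells without any count of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, 683 cells had Y-linked counts without Xist, 111 had both and 213 neither. Independent detection would give 272 cells with both, and the ratio of observed to expected ranged from 0.282 to 0.601 over the 7 libraries, which is consistent with MEFs pooled from male and female embryos. Xist overlaps Tsix on the other strand, and the counting could mix the pair. Cells with Y-linked counts alone made up 48.2% to 53.5% of clusters 1 to 6 and 34.0% of the 53 cells of cluster 7, a difference that was not tested.

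Each of the unnamed clusters was set against all other cells on the held-out counts, and no test was run between clusters. Contractile genes fell in 9 of 10 cases in cluster 3 (9 adjusted over the list alone) and in 10 of 10 in clusters 4, 5 and 6 (10 each). The cells they were set against held cluster 2, where all 10 rose, and 7 of 10 fell in cluster 1 as well. These falls are therefore not particular to the unnamed clusters. In the same way, the lower Top2a of clusters 2, 4 and 5 was measured against cells that included cluster 1. In cluster 4, 7 of 14 glycolysis genes rose (9 adjusted over the list alone; camera adjusted p = 4.39e-06, and adjusted p = 0.0169 with an estimated correlation) and 5 of 7 mitochondrially encoded genes rose with them (7 adjusted over the list alone; adjusted p = 8.09e-06, and adjusted p = 0.129 with an estimated correlation). The latter can come from RNA quality, and cluster 4 had the lowest depth. In cluster 5, 9 of 11 imprinted growth genes rose (9 adjusted over the list alone) with a median log2 fold change of 0.63 (camera adjusted p = 9.83e-10, and adjusted p = 0.0402 with an estimated correlation), and 3 of 6 interferon response genes rose (5 adjusted over the list alone; adjusted p = 0.000139, and adjusted p = 0.0236 with an estimated correlation). The leading genes of cluster 6 by fold, named here after their values were seen, included the transcription factors Zic4 and Zic1, which pattern the dorsal midline.

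Barcodes within a library that differed at 1 position formed 14 pairs, against 0.418 expected from pairs across libraries, and 12 of the 14 lay in the same cluster, against 18.5% of all pairs within a library. With up to 2 differences there were 21 pairs, against 4.18 expected. Of all barcodes, 14.5% ended in N. Some pairs may be 1 bead counted as 2 cells, as an excess of 14 over 0.418 allows, so the 1362 barcodes are an upper count of cells in this respect; all were kept.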
